A study of Rattus norvegicus with 47 samples.

How the data were processed

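Total RNA from the medial prefrontal cortex of Wistar rats was labelled with biotin and hybridised to 1-colour Affymetrix arrays, from 7 ug of RNA per sample, per the labels' protocols. The deposited table holds 20304 probe sets on 47 arrays. Its values are log2 signals: powers of 2 of the deposited values are whole multiples of a linear signal given to 2 decimals. The signals were computed by the authors with MAS5, per the submitters' processing notes; no version and no scaling target are given in the sources used here. The arrays had been scaled before they were deposited, since their trimmed mean signals (2% trimmed) lay between 156.59 and 161.44, a ratio of 1.03, and no further normalization was applied. A second deposited text lists 14 filtering criteria of the authors with the number of probe sets that passed each. Those numbers are counts of probe sets. In the authors' deposited table the limits on the p-value (up to 1.0) and on the fold (above 1.0) let all 31099 probe sets through, so the deposited set was chosen by presence calls (present or marginal in at least 25% of the arrays of a group) and group means above 1.5, which 20304 probe sets passed in any of the 4 comparisons of rearing. Batch, hybridisation date and sex are not given in the labels.

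Groups were taken from the labels' rearing and age. Arrays of a group were compared before averaging by the root mean square distance of their log2 values. Arrays 3 and 4 of the isolation-reared group at P30 lay 0.116 apart, 0.488 of the group's median distance (0.237). All others of the 115 pairs within groups lay at 0.175 or more, and at 0.863 or more of their group's median, and the distance of the pair over 16 spike-in probe sets (0.0613) was also under that of every other pair (0.0919 or more). The mean of those arrays was counted as 1 sample, so 46 samples entered each fit. The limit (0.6 of the group median) and this step were chosen after the data, and a first complete analysis with all 47 arrays, had been seen; all 47 arrays counted apart is 1 of the alternatives. Over the 16 spike-in probe sets, array 4 of the isolation-reared group at P80 lay 4.05 to 4.56 from the other arrays of its group. By the distance used for the comparison of arrays it lay 0.226 to 0.268 from them, and the cause was not tested. The number of arrays limits the precision.

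Probe sets were kept where the mean log2 signal reached the 40th percentile of the 20249 probe sets that are not controls (5.72), which left 12149. Gene symbols came from the deposited platform annotation, checked by gene number against a rat gene table of the assembly GRCr8, which served for names alone: 14567 probe sets matched it and no symbol changed. Of the probe sets, 14613 had 1 gene symbol, 326 had several and were not named, and 5316 that are not controls had none listed. The kept probe sets named 7898 genes.

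The model was limma (version 3.58.1, R 4.3.3): 8 group means, variances moderated with a trend, 38 residual degrees of freedom, two-sided tests, and Benjamini-Hochberg adjustment within each comparison at 0.05. The comparisons were isolation against social rearing at each age, their mean over the 4 ages with equal weights, the interaction of rearing with age (a moderated F test), the age steps in socially reared rats, and P80 against P30 in either rearing. The 34 gene lists, with 761 entries, were fixed before the data were examined, as were the tests, the threshold, the filter and the rule for named genes. Of these, 30 lists with at least 4 measured genes were tested with camera in limma against all other genes, with a preset correlation of 0.01 between genes and again with an estimated correlation, 1 probe set per gene (that of highest mean), Benjamini-Hochberg adjusted over the 30 lists of a comparison. Named genes were, per rearing comparison, for their mean and for P80 against P30 in socially reared rats, the 12 largest rises and the 12 largest falls among called probe sets with 1 gene, each gene through its probe set of smallest p; for other age steps 5 and 5; for the interaction the 10 smallest p; and up to 4 members of each list by p. Where other probe sets of a gene were called in the opposite direction, this is said beside the gene. Array quality was compared by exact two-sided permutation tests. The hexokinase 3' to 5' ratio was not among the quality measures fixed beforehand. Correlations of effects between comparisons were set against 100 swaps of the rearing labels within each age. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

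The fit was tested on simulated data for isolation against social rearing at P60, in 12149 probe sets of which 200 were changed. It recovered 44.8% of those changed 1.2-fold, 89.6% of those changed 1.5-fold and 100% of those changed 2-fold, with 8 false among 164 calls. The simulated groups differed by array noise and the planted changes alone, so these rates do not cover differences between pools or runs. For the mean over the 4 ages with group means as the unit, 83.6% of probe sets changed 1.2-fold were recovered where groups differed by array noise alone.

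Alternatives fixed beforehand were small and large pseudocounts (4.115 and 65.84 added to the linear signal), no filter and a filter at the 70th percentile, quantile normalization, a variance prior without trend, fits to the compared groups alone, a replicate block, the Gapdh 3' to 5' ratio as a covariate, each array left out in turn, the authors' kind of test on the same values, the estimated correlation in list tests, and list tests on the mean of all probe sets of a gene. Chosen after seeing the data were group means as the unit (for probe sets, for lists with camera, and for the list means of the 8 groups in limma with and without moderated variances), leaving out the 3 arrays farthest from their group means, a size limit of 0.5 on the log2 difference, and the close arrays counted apart.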

Results

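Gene expression was measured in the medial prefrontal cortex, a frontal region with a part in social and executive behaviour, of Wistar rats, an outbred laboratory strain. The rats had been reared socially (Soc) or in isolation (Iso), and tissue was taken at postnatal day 30, 40, 60 or 80 (P30, P40, P60, P80), from adolescence to adulthood. Each of the 8 groups held 6 arrays, except Iso P40 with 5. In Iso P30, arrays 3 and 4 differed by less than the noise between other replicate arrays (0.116 log2, root mean square, against 0.175 or more for every other pair within a group) and were counted as 1 sample, a step chosen after the data had been seen. The tests thus rested on 46 samples from 47 arrays, and Iso P30 had n = 5. Of the probe sets, 14613 had 1 gene symbol, 326 had several and 5316 had none listed. The labels do not say that the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. All differences are isolation minus social, or older minus younger, on the log2 scale, from the fit with limma.

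Samples of a group lay close together. The nearest neighbour of each of the 46 samples belonged to its own group, at a median distance of 0.222 log2 within groups against 0.327 between groups. The ratio of the 3' to the 5' signal of the Gapdh control probe sets, which rises with RNA degradation, also differed by rearing at every age. It was lower in Iso at P30 (1.34 ± 0.064 (SD, n = 5) against 1.52 ± 0.042 (SD, n = 6), exact permutation p = 0.00216, adjusted p = 0.0072), P60 (1.36 ± 0.039 against 2.03 ± 0.15, n = 6 each, exact p = 0.00216, adjusted p = 0.0072) and P80 (1.57 ± 0.091 against 1.89 ± 0.091, n = 6 each, exact p = 0.00216, adjusted p = 0.0072). At P40 it was higher in Iso (1.87 ± 0.097 (n = 5) against 1.61 ± 0.091 (n = 6), exact p = 0.00433, adjusted p = 0.0108). The smallest p these designs allow is 0.00216. The other 3' to 5' controls differed less evenly. The actin ratio was lower in Iso at P30 (adjusted p = 0.0108) and P60 (adjusted p = 0.0072) and did not pass at P40 (adjusted p = 0.538) or P80 (adjusted p = 0.0505). The hexokinase ratio passed only at P80, where it was higher in Iso (3.32 against 2.44, adjusted p = 0.0173), opposite to Gapdh. The median linear signal of the arrays differed by rearing at every age in the same permutation test (adjusted p from 0.0072 to 0.0315). It was higher in Iso at P30 and P60 (by 2.47 and 2.83) and lower at P40 and P80 (-2.09 and -1.54). On the first principal components Iso P80 overlapped Soc P60. Whether labels of whole groups had been exchanged was not tested, and an exchange would change what the differences at P60 and P80 mean.

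**Figure D1:**
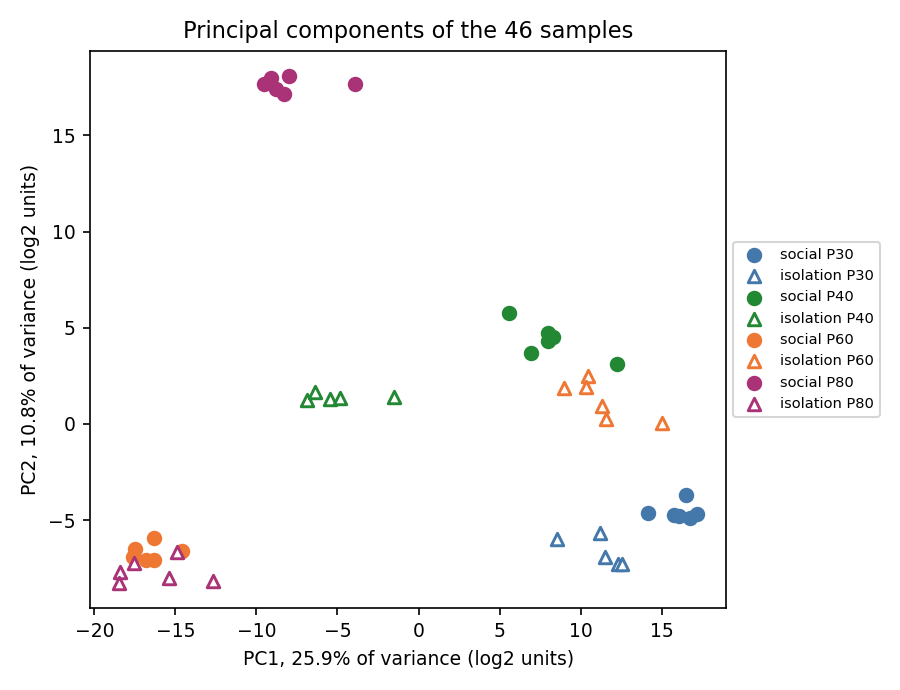
First principal component (x axis, 25.95% of variance) and second principal component (y axis, 10.75% of variance) of the 46 samples, in log2 units, with filled circles for social and open triangles for isolation rearing, coloured by age. Samples of a group lie together, and Iso P80 overlaps Soc P60 on these axes.

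The first question was how isolation rearing differed from social rearing at P30. Genes that neurons switch on within minutes of activity were lower in isolated rats: Fos fell by 1.79 ± 0.096 (SE), from 7.98 ± 0.12 (SD, n = 6) in Soc to 6.19 ± 0.21 (n = 5) in Iso, 3.46-fold lower, and Egr2, Arc, Nr4a1 and Egr1 fell by 1.55, 1.48, 0.92 and 0.78 (limma adjusted p from 9.79e-20 for Fos to 1e-31 for Arc). The change of largest size was in Ttr, the carrier of thyroid hormone and retinol made in the choroid plexus, which was 8.66-fold lower in Iso (6.58 ± 0.28 against 9.70 ± 0.087, adjusted p = 1.44e-27). Genes of synaptic vesicles and several neuropeptides were lower as well. In all, 2418 of 12149 probe sets passed, 925 higher and 1493 lower in Iso, of which 136 differed by over 0.5 (66 higher, 70 lower).

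Of 17 measured immediate early genes at P30, 12 fell and 5 did not pass, with 13 lower when adjusted over the list alone (median -0.58, camera adjusted p = 2.91e-67, and 3.09e-12 with an estimated correlation). Dusp1, a phosphatase of MAP kinases, and the transcription factor Klf10 fell by 0.95 and 0.69. In the presynaptic and vesicle list 14 of 20 members fell, 1 rose and 5 did not pass (15 lower and 1 higher adjusted over the list alone, median -0.22, adjusted p = 2.87e-11, and adjusted p = 0.00642 with an estimated correlation). They included Syngr3 (-0.38), the vesicle fusion protein Vamp2 (-0.30), the vesicle GTPase Rab3a (-0.35) and the fusion protein Stx1a (-0.23). Of 12 stress and social neuropeptide genes, 6 fell and 6 did not pass, 8 lower adjusted over the list alone (adjusted p = 0.0142, and 0.00787 with an estimated correlation). The somatostatin receptor Sstr1 (-0.20), corticotropin-releasing hormone Crh (-0.45), its binding protein Crhbp (-0.28) and prodynorphin Pdyn (-0.66) were among those that fell. The myelin list went the other way in a minority of its members, with 7 of 24 higher, led by Mog (0.31), Lpar1 (0.28), Evi2a (0.29) and Gsn (0.17), and 17 not passing (9 higher and 1 lower adjusted over the list alone, median 0.016, adjusted p = 0.0192, and 0.0394 with an estimated correlation).

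Other lists at P30 passed with the preset correlation and not with an estimated one. Of 18 astrocyte genes 9 fell and 1 rose (10 and 1 adjusted over the list alone, adjusted p = 0.0142, and adjusted p = 0.212 with an estimated correlation). Clu (-0.30), Gfap (-0.17) and S100b (-0.22) fell, and Fabp7 rose by 0.25. Among 8 GABA receptor genes 3 fell, Gabrb2 (-0.23), Gabbr2 (-0.24) and Gabra5 (-0.19), also adjusted over the list alone (adjusted p = 0.0473, and adjusted p = 0.0807 with an estimated correlation). The heat shock and chaperone list had 4 of 12 lower, Hsp90ab1, Hspd1, Hspa5 and Ahsa1 at -0.25, -0.18, -0.19 and -0.16 (5 adjusted over the list alone, adjusted p = 0.0142, and adjusted p = 0.0664 with an estimated correlation). In the immature neuron and neurite growth list 5 of 15 fell and 2 rose (7 and 2 adjusted over the list alone, adjusted p = 0.0473, and adjusted p = 0.284 with an estimated correlation). Crmp1 stood at -0.30, Cd24 at -0.36 and Sox4 at 0.28. Of 43 oxidative phosphorylation genes 10 fell (12 lower and 1 higher adjusted over the list alone; adjusted p = 0.0378, and adjusted p = 0.643 with an estimated correlation), and the direction of this list flipped after quantile normalization (adjusted p = 0.504); Atp5pb and Uqcrfs1 each stood at -0.26. The interferon list had 2 of 8 lower, Irf7 (-0.63) and Ifi27 (-0.24), the same 2 adjusted over the list alone (adjusted p = 0.0473, and adjusted p = 0.146 with an estimated correlation).

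The largest rises at P30 were in Anp32a, an acidic nuclear phosphoprotein (3.38-fold, 7.74 ± 0.13 against 5.98 ± 0.34), Vdac1, the pore of the outer mitochondrial membrane (1.32), Pcnp (1.11) and the endoplasmic reticulum chaperone Hyou1 (0.97). The class I histocompatibility gene RT1-T24-4 (0.90), the spectrin Sptbn1 (0.89), the cofilin kinase Limk1 (0.82), Larp6 (0.79), the postsynaptic scaffold Dlg4 (0.78), Zfp410 (0.77), Harbi1 (0.76) and radixin, Rdx (0.75), followed. Further falls were in R3hdm2 (-0.87), the coenzyme A synthesis enzyme Pank3 (-0.85), Armc9 (-0.73) and the helicase Dhx36 (-0.71), for which another probe set passed in the opposite direction. Markers of the choroid plexus and ependyma other than Ttr lay below the signal filter. Folr1 had 5.56 ± 0.22 in Iso and 5.13 ± 0.32 in Soc, and Sostdc1 4.47 ± 0.52 and 5.06 ± 0.24. Kcne2 had 4.97 and 4.52, and Foxj1 4.37 and 4.32. Over all groups Sostdc1 was highest in Iso P40 (5.08) and Soc P30, where Ttr was high as well, and Folr1, Kcne2 and Foxj1 did not follow Ttr. Whether the amount of choroid plexus in the samples differed between groups was not tested. With the Gapdh 3' to 5' ratio, which was lower in Iso at P30, as a covariate, 1589 probe sets passed.

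**Figure D2:**
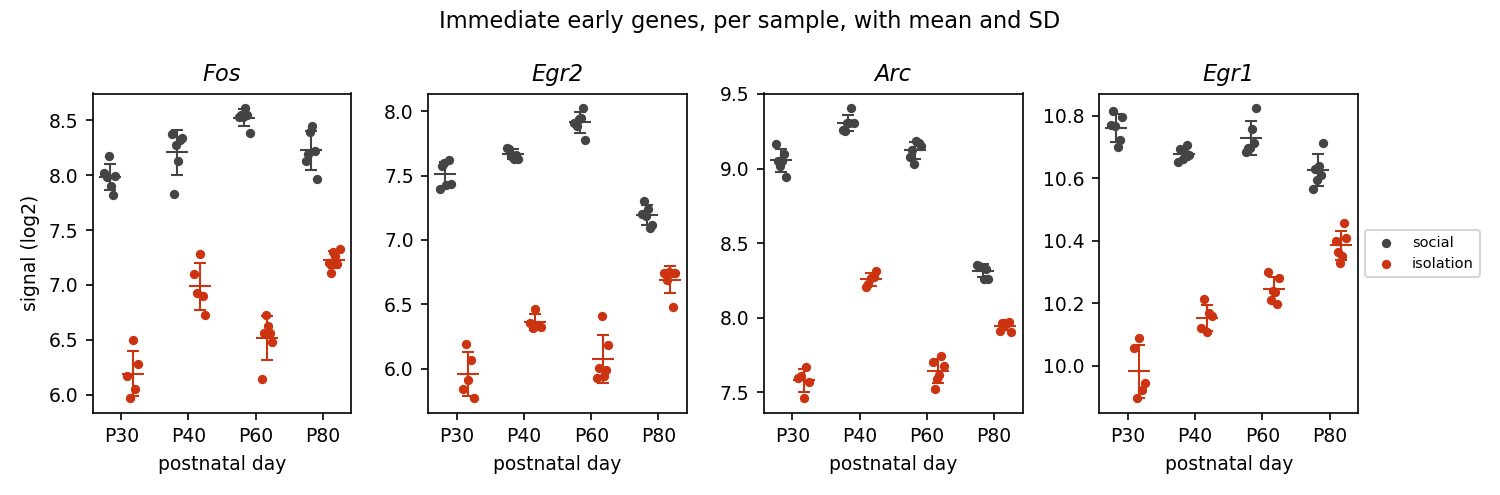
Signal (y axis, log2) of Fos, Egr2, Arc and Egr1 per sample against postnatal day (x axis), with social rearing in grey and isolation rearing in red, and bars for the mean and SD. At each age the mean of the isolation group lies below that of the social group, by -1.79, -1.22, -2.01 and -0.995 for Fos from P30 to P80.

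The second question was the same comparison at P40. Here the genes induced by interferon were far lower in isolated rats: Irf7, the transcription factor that drives the interferon response, was 5.44-fold lower (5.84 ± 0.16 (SD, n = 5) in Iso against 8.28 ± 0.060 (n = 6) in Soc, adjusted p = 4.01e-27) and the ubiquitin-like Isg15 was 4.34-fold lower (5.53 ± 0.36 against 7.64 ± 0.089, adjusted p = 3.76e-13). Irf9, part of the factor that relays interferon signals, and Ifit2 fell by 1.44 and 1.41. The mean over the interferon list was 8.15 in Soc P40 and 6.89 in Iso P40, and lay between 6.815 and 6.957 in the groups of P30 and P60. The group that stood apart was thus Soc P40, and Iso P40 lay near the level of those other groups. Ttr was now higher in Iso, 3.91-fold (8.01 ± 0.11 against 6.05 ± 0.20, adjusted p = 8.85e-20). Immediate early genes were again lower, and so were myelin genes. In all, 3443 probe sets passed, 1671 higher and 1772 lower, with 62 higher and 298 lower by over 0.5.

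In the interferon and antigen presentation list 7 of 8 members fell and Stat2 (-0.14) did not pass, the same 7 adjusted over the list alone (median -1.37, adjusted p = 5.42e-61, and 2.61e-09 with an estimated correlation). Class I histocompatibility genes RT1-S3 (-1.56) and RT1-T24-3 (-1.47) and the secreted Lgals3bp (-1.67) fell with them. RT1-T24-4 rose by 2.52 from a variable level in Soc (3.73 ± 1.10) below the 10th percentile of all signals, so that the size of this rise is not known. Of 17 immediate early genes 9 fell, 1 rose and 7 did not pass (10 lower and 1 higher adjusted over the list alone, median -0.27, adjusted p = 4.92e-28, and 6.86e-09 with an estimated correlation). Arc, Nr4a1, Egr2 and Egr1 stood at -1.05, -0.81, -1.30 and -0.53. The mature oligodendrocyte and myelin list had 16 of 24 lower and 8 not passing, also adjusted over the list alone (median -0.20, adjusted p = 1.44e-10, and 2.56e-07 with an estimated correlation). Among them were Mal (-0.44), the galactolipid enzyme Ugt8 (-0.60), Cryab (-0.47) and the myelin enzyme Cnp (-0.25). Microglial genes fell in 4 of 10 cases and rose in 1 (the same numbers adjusted over the list alone, adjusted p = 0.0155, and 0.0327 with an estimated correlation). The complement components C1qa (-0.53), C1qc (-0.64) and C1qb (-0.49) fell, and P2ry12, a receptor of resting microglia, rose by 0.34. In the perineuronal net and extracellular matrix list 5 of 11 fell and 1 rose (7 and 1 adjusted over the list alone, adjusted p = 0.0264, and 0.0362 with an estimated correlation). Sparc stood at -0.64, Cspg5 at -0.32, Timp2 at -0.15 and reelin, Reln, at 0.18.

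Presynaptic genes fell in 10 of 20 cases at P40 and rose in 2 (12 and 2 adjusted over the list alone, median -0.13, adjusted p = 1.65e-06, and adjusted p = 0.0438 with an estimated correlation). The calcium sensor Syt1 (-0.68), the active zone protein Rims1 (-0.66), Amph (-0.44) and the vesicle glycoprotein Sv2a (-0.42) led them. Of 30 cytosolic ribosomal protein genes 12 fell and 18 did not pass, also adjusted over the list alone (adjusted p = 2.34e-06, and adjusted p = 0.283 with an estimated correlation). Rplp0 (-0.32) and Rpl4 (-0.28) led them. In the astrocyte list 5 of 18 fell, also adjusted over the list alone (adjusted p = 0.0425, and adjusted p = 0.293 with an estimated correlation), including Clu (-0.31), Gfap (-0.19) and the glutamate transporter Slc1a2 (-0.49). Other large rises were in the sphingolipid desaturase Degs1 (0.99), Arxes2 (0.84), Zfp329 (0.77), Thoc2 (0.69), Myef2 (0.67), Borcs8 (0.65, and 0.32 without 1 low array of Soc), Bex2 (0.65), the gap junction gene Gjb2 (0.65), the malic enzyme Me2 (0.64) and Rasgef1c (0.63). Falls outside these lists were in Poldip2 (-1.52, and -1.01 without 1 low array of Iso), the phosphatase Ppm1a (-1.47, and -0.92 without 1 low array of Iso), Rab8b (-1.45), the chaperone calnexin, Canx (-1.43), and the sodium pump subunit Atp1b2 (-1.43). The Gapdh 3' to 5' ratio was higher in Iso at this age. The authors' kind of test, run separately per probe set, passed 2266 probe sets after Benjamini-Hochberg adjustment.

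**Figure D3:**
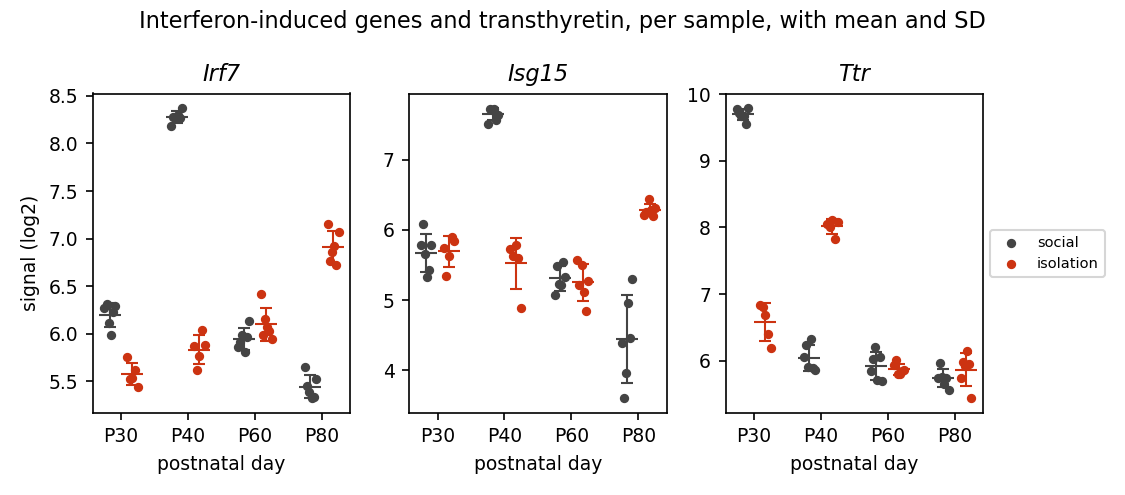
Signal (y axis, log2) of Irf7, Isg15 and Ttr per sample against postnatal day (x axis), with social rearing in grey and isolation rearing in red, and bars for the mean and SD. Irf7 is highest in Soc P40 (8.28) and next highest in Iso P80 (6.92), and Ttr is high in Soc P30 (9.70) and Iso P40 (8.01) and lies between 5.73 and 6.58 in the other groups.

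At P60 more probe sets differed by rearing than at any other age, an order lost with the Gapdh 3' to 5' ratio as a covariate (3752 at P60 against 4226 at P80). Fos was 4.03-fold lower in isolated rats (6.52 ± 0.20 against 8.52 ± 0.077 (SD, n = 6 each), adjusted p = 9.86e-23), Egr2 3.57-fold lower, and Dusp1 and Arc fell by 1.52 and 1.48. Large rises were in the endocytic adaptor Epn1 (2.82-fold, 7.72 ± 0.16 against 6.22 ± 0.19, adjusted p = 5.57e-19), the fusion clamp Cplx1 (2.72-fold, adjusted p = 8.67e-21; its brightest probe set, at 0.05, did not pass), the GTPases Rab3a (1.21, and 0.29 in its other probe set) and Rab1b (1.26), and the endophilin Sh3gl2 (1.16). In all, 6446 of 12149 probe sets passed, 2881 higher and 3565 lower, with 713 higher and 288 lower by over 0.5.

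Of 17 immediate early genes 15 fell at P60 and 2 did not pass, also adjusted over the list alone (median -0.64, adjusted p = 1.02e-28, and 3.46e-08 with an estimated correlation). The presynaptic list had 11 of 20 higher and 3 lower, also adjusted over the list alone (median 0.13, adjusted p = 0.00224, and adjusted p = 0.682 with an estimated correlation). Syt1 (0.79), Stx1a (0.41), Amph (0.56) and Sv2a (0.48) were opposite in sign to their values at P40 or P30. No other list passed at P60 with the values as deposited, though many members did, in both directions. After quantile normalization the oxidative phosphorylation list (adjusted p = 0.0028) and the ribosomal protein list (adjusted p = 0.00587) passed as well. Among 14 interneuron genes 6 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.953). Parvalbumin, Pvalb, rose by 0.82 and cholecystokinin, Cck, by 0.42, and Vip and the GABA synthesis enzyme Gad1 fell by 0.45 and 0.26. In the oxidative phosphorylation list 17 of 43 rose and 10 fell (17 and 12 adjusted over the list alone, adjusted p = 0.17), with Uqcrfs1 (0.54), Sdhb (0.45), Atp5f1d (0.47) and Uqcrh (-0.51). Clock genes included Dbp, higher by 0.70, and Per2, at -0.46 (2 of 12 rose and 4 fell, also adjusted over the list alone, adjusted p = 0.864).

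Further rises at P60 were in Agap3 (1.51), Minar2 (1.26), beta-synuclein, Sncb (1.19), Pls3 (1.17), the synaptotagmin Syt4 (1.16), the amyloid precursor App (1.15) and the potassium channel subunit Kcnab2 (1.15); another probe set of Minar2 and of Syt4 passed in the opposite direction. Further falls were in Catsperz (-0.97), the transcriptional inhibitor Id4 (-0.96), Arap1 (-0.95), Srek1ip1 (-0.90), the protease inhibitor Reck (-0.90), Cryl1 (-0.90), Rnpc3 (-0.88) and Egr4 (-0.88). The Gapdh 3' to 5' ratio was lower in Iso (difference -0.67), the widest gap of the 4 ages.

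At P80 interferon genes were higher in isolated rats, opposite to P40. Isg15 was 3.57-fold higher (6.28 ± 0.090 against 4.44 ± 0.62 (SD, n = 6 each), adjusted p = 1.95e-12), Irf7 2.77-fold higher (6.92 ± 0.17 against 5.45 ± 0.12, adjusted p = 2.36e-19), and Irf9, Lgals3bp, the antiviral Rsad2 and RT1-T24-3 rose by 1.12, 1.09, 0.94 and 0.78. For Isg15 the Soc samples lay between 3.60 and 5.30, under the filter level of 5.72, so the size of its rise is uncertain. Fos fell by 0.995 (0.092 SE), and Epn1, the endocytic adaptor that was higher at P60, fell by 0.99. In all, 5796 probe sets passed, 2852 higher and 2944 lower, with 247 higher and 409 lower by over 0.5.

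The interferon list had 7 of 8 members higher at P80 and Stat2 (0.16) not passing, the same 7 adjusted over the list alone (median 0.82, adjusted p = 1.01e-10, and 0.000329 with an estimated correlation); Ifi27 and the class I light chain B2m rose by 0.50 and 0.47. Of 24 myelin genes 11 fell, 3 rose and 10 did not pass (12 and 3 adjusted over the list alone, median -0.14, adjusted p = 0.0208, and 0.048 with an estimated correlation). This call was lost with the mean of all probe sets of a gene (adjusted p = 0.0643). The actin-severing Gsn (-0.52), Mal (-0.40), Plekhb1 (-0.50) and Enpp2 (-0.32) were examples. The immediate early list missed the threshold (7 of 17 fell and 1 rose, 9 and 2 adjusted over the list alone, median -0.16, adjusted p = 0.0533, and 0.0708 with an estimated correlation), and passed after quantile normalization (adjusted p = 0.0354). Arc, Egr1 and Egr2 still fell by 0.37, 0.24 and 0.50. Neuronal adhesion genes changed in both directions (11 of 20 fell and 4 rose, also adjusted over the list alone, adjusted p = 0.371). The cadherin Cdh10 (0.42) rose, and L1cam (-0.38), the neurexin Nrxn3 (-0.73) and Alcam (-0.57) fell. Of 12 glutamate receptor genes 6 fell, also adjusted over the list alone (adjusted p = 0.458), including Grik5 (-0.28), Gria3 (-0.23), Grik2 (-0.47) and Grin2a (-0.54).

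Other rises at P80 were in the G protein subunit Gnas (1.05), Mmgt1 (0.83), the cytochrome oxidase assembly factor Coa5 (0.81), Ppp1r26 (0.79), Rapgef5 (0.78) and Vwc2 (0.78). Akap8l (-1.40), the ubiquitin ligase subunit Fbxw7 (-1.26), Ptov1 (-1.22), the neurofilament protein Ina (-1.08, with another probe set passing in the opposite direction), Zcchc17 (-1.05), the retinoid receptor Rxrb (-1.001), the poly(A)-binding Pabpn1 (-0.99), the transcription factors Nfib (-0.98) and Foxj2 (-0.97) and the noncoding Snhg11 (-0.96) fell. The Gapdh 3' to 5' ratio was lower in Iso, and haemoglobin Hbb, a marker of blood, was lower as well (9.18 ± 0.090 against 9.65 ± 0.073).

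Averaged over the 4 ages, the difference that stood out was again in genes of neuronal activity. Fos fell by 1.504 ± 0.047 (SE), Egr2 by 1.30 ± 0.035 and Arc by 1.09 ± 0.019 (adjusted p = 2.18e-29, 4.81e-32 and 7.81e-40). Next came Dusp1 (-0.80), Egr4 (-0.66), Nr4a1 (-0.64), the prostaglandin synthase Ptgs2 (-0.57), the ERK phosphatase Dusp6 (-0.52), Klf2 (-0.52) and Egr1 (-0.51). In all, 3472 probe sets passed, 1502 higher and 1970 lower, and only 18 by over 0.5, 3 higher and 15 lower. Of 17 immediate early genes 15 fell, also adjusted over the list alone (median -0.39, adjusted p = 4.61e-118, and 6.62e-14 with an estimated correlation). Myelin genes fell in 14 of 24 cases (15 adjusted over the list alone, median -0.10, adjusted p = 1.93e-06, and 4.15e-05 with an estimated correlation). They included Tspan2 (-0.22), Mal (-0.16), Cryab (-0.27) and Enpp2 (-0.16). With group means as the unit the myelin list passed with camera (adjusted p = 5.94e-05), and its mean did not differ by rearing over the 8 groups in limma (adjusted p = 0.947). Of 20 presynaptic genes 8 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.0165, and adjusted p = 0.332 with an estimated correlation), with Syngr3, Napb and Vamp2 at -0.13, -0.13 and -0.12. Of 8 interferon genes 3 fell, Ifi27 (-0.18), Irf7 (-0.36) and Ifit2 (-0.31), also adjusted over the list alone (adjusted p = 0.0173, and adjusted p = 0.121 with an estimated correlation).

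The largest rises of the mean were smaller: RT1-T24-4 (0.78, resting on P40, where its level in Soc lay below the 10th percentile of all signals), Harbi1 (0.50), Degs1 (0.41), Larp6 (0.39), the haematopoietic Hcls1 (0.38), Armcx6 (0.37), Gmds (0.34), the muscarinic receptor Chrm3 (0.33), the annexin Anxa3 (0.33), Anp32a (0.32, from 1.76 at P30 alone, with -0.43 at P80), the calcium sensor Ncs1 (0.32) and the ceramidase Asah1 (0.32); the plexin Plxna4 (-0.46) and Dhx36 (-0.50, with another probe set passing in the opposite direction) completed the falls. Few probe sets kept 1 direction: 945 (7.78%) had the same sign at all 4 ages, fewer than the 12.5% that independent signs would give, and 21 also passed at each age, 16 lower and 5 higher in Iso. The lower ones included Fos, Egr2, Arc, Nr4a1, Egr1, Ptgs2, Dusp6, Klf2 and 2 of the 4 probe sets of the synaptic scaffold Homer1 (-0.97 and -0.59 at P30), and the higher ones Rnasek, Nop10, Polr2j and Dut. With the 8 group means as the unit in limma, which counts the arrays of a group as 1 value, 0 probe sets passed and 210 had an unadjusted p under 0.05, with the smallest adjusted p for Fos (0.0528). With the Gapdh 3' to 5' ratio as a covariate 1860 passed.

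**Figure D4:**
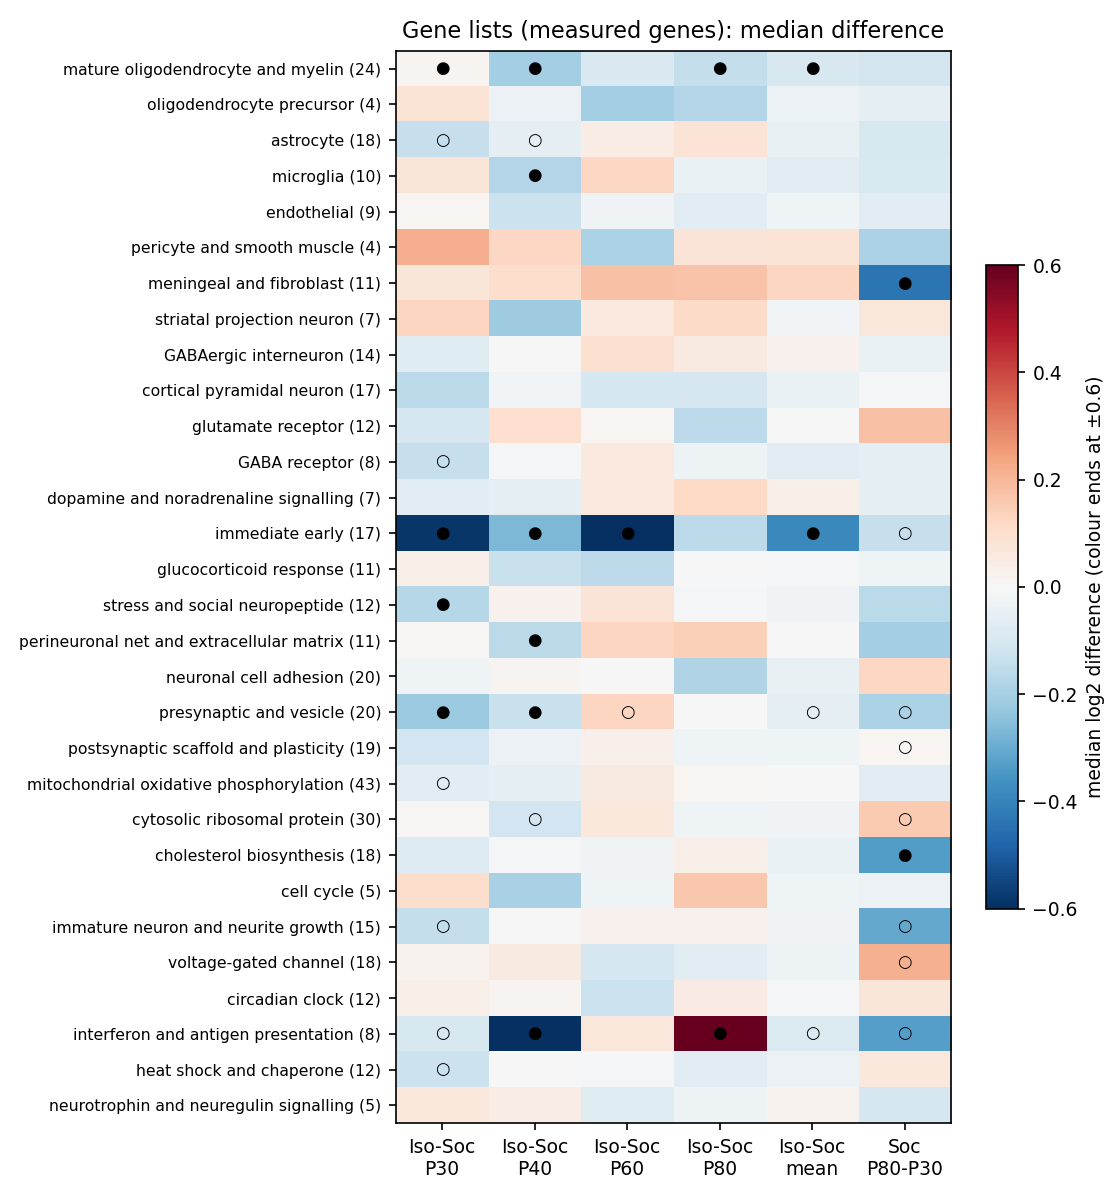
Median log2 difference (colour) of the measured genes of each of 30 lists (number of genes in brackets) in 6 comparisons, with a filled dot where camera passed also with an estimated correlation and an open dot where it passed with the preset correlation alone. The immediate early list is lowest at P30 and P60 (medians -0.58 and -0.64), and the interferon list turns from -1.37 at P40 to 0.82 at P80.

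Whether the difference by rearing varied between ages was tested by the interaction, which passed for 8767 of 12149 probe sets. Each rearing at each age was a single group, and the test rests on the spread between arrays of a group. An interaction thus cannot be told apart from other differences between groups, such as pools or runs. With group means as the unit it could not be tested, as no spread would be left. The 10 genes of smallest p were Ifi27, Ttr, Rab3a, Irf7, the calcium sensor Vsnl1, the synapsin Syn2, the myelin genes Mobp and Mbp, Vdac1 and the desaturase Scd2 (adjusted p from 5.67e-32 to 1.03e-24). Values here are those of the probe set of smallest p. Rab3a stood at -0.17, -0.32, 1.21 and -0.04 from P30 to P80, and at -0.35, -0.17, 0.29 and -0.13 in its other probe set, the one given for P30 above. Syn2 stood at -0.47, -0.55, 0.85 and -0.01, and another of its probe sets passed in the opposite direction at P40 (0.21) and P60 (-0.30). Myelin basic protein, Mbp, stood at 0.14, -1.09, 0.75 and 0.31, whereas its brighter probe set stood at -0.19, -0.26, 0.01 and 0.04 and passed only at P40. Mobp, Scd2 and Vdac1 were likewise lower in Iso at P40 and higher at P60 (-1.06 and 0.63, -0.88 and 0.49, -1.10 and 1.02). Other probe sets of Mobp (-0.52) and Scd2 (-0.56) were lower at P60, opposite to these. Across probe sets, which are not independent replicates, the rearing differences at P40 and P60 were inversely related (r = -0.491, rho = -0.502, 31.4% with the same sign, range of r over 100 label swaps -0.444 to 0.346, adjusted p = 0.033 over 10 relations), as were those at P60 and P80 (r = -0.319, rho = -0.384, adjusted p = 0.033). Were the rearing labels exchanged at P60, these signs would turn and all 6 relations between ages would be positive, and Fos, Egr2 and Arc would be higher in Iso at that age. Those at P30 and P80 were weakly related (r = 0.225, rho = 0.254, adjusted p = 0.033), a call lost with the filter at the 70th percentile (r = 0.276, adjusted p = 0.066). For all of these, 0.0099, the unadjusted p with the values as reported, is the smallest that 100 swaps can give. The Gapdh 3' to 5' ratio also differed by rearing in opposite directions at P40 (0.26) and P60 (-0.67), but alike at P60 and P80 (-0.32). The relations were not tested with this ratio as a covariate. The pairs P30 and P40 (r = 0.205), P40 and P80 (r = 0.178) and P30 and P60 (r = -0.101) did not pass (adjusted p = 0.066, 0.066 and 0.186), nor did the relations of the rearing difference with an age step in socially reared rats (r = -0.109, -0.194, -0.0812 and -0.0308 at P30, P40, P60 and P80).

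Ages were next compared within socially reared rats. Each age was a single group, so maturation cannot be told apart from other differences between groups, such as pools or runs. Between P30 and P80, 11 of 18 cholesterol synthesis genes and 6 of 11 meningeal genes fell. Ttr was 15.6-fold lower at P80 (5.73 ± 0.13 against 9.70 ± 0.087 (SD, n = 6 each), adjusted p = 1.01e-32), the astrocyte glutamate transporter Slc1a3 fell by 1.39 (0.46 in its brightest probe set) and the vesicle fusion ATPase Nsf by 1.33. The axonal potassium channel Kcna1 rose by 1.28 and the transcription factor Nfib by 1.201. In all, 6044 probe sets passed, 3187 higher and 2857 lower at P80, with 505 higher and 568 lower by over 0.5. In Iso, Ttr was lower at P30 (6.58) than at P40 (8.01), so its level did not follow age alone.

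Of 18 cholesterol synthesis genes 11 fell and 1 rose (12 and 1 adjusted over the list alone, median -0.34, adjusted p = 1.38e-07, and 0.0065 with an estimated correlation). Cyp51 (-0.54), Dhcr7 (-0.59), the squalene synthase Fdft1 (-0.42) and Sqle (-0.59) were among those lower. The meningeal and fibroblast list had 6 of 11 lower (8 adjusted over the list alone, median -0.44, adjusted p = 0.00441, and 0.0159 with an estimated correlation), with the prostaglandin D synthase Ptgds (-0.59) and the collagens Col1a1 (-0.84) and Col3a1 (-0.51). Of 15 genes of immature neurons and neurite growth 13 fell and 2 rose, also adjusted over the list alone (median -0.31, adjusted p = 0.000298, and adjusted p = 0.112 with an estimated correlation). Cd24 (-0.73), Marcksl1 (-0.40) and Stmn2 (-0.32) were lower and Tubb3 (0.45) was higher. Voltage-gated channels rose in 11 of 18 cases and fell in 2, also adjusted over the list alone (median 0.21, adjusted p = 0.00765, and adjusted p = 0.126 with an estimated correlation). Kcna2 (0.59), Scn4b (0.46), Scn1a (0.38) and Kcna1 (1.28) rose. Presynaptic genes fell in 11 of 20 cases and rose in 3 (13 and 3 adjusted over the list alone, adjusted p = 6.09e-05, and adjusted p = 0.123 with an estimated correlation), with Syt1 at -1.11 and Rims1 at -0.96. Ribosomal protein genes rose in 16 of 30 cases and fell in 1, also adjusted over the list alone (adjusted p = 0.00693, and adjusted p = 0.52 with an estimated correlation), with Rpl12 and Rpl18 at 0.30 and 0.33. The immediate early list had 8 of 17 lower and 4 higher, also adjusted over the list alone (adjusted p = 0.00441, and adjusted p = 0.112 with an estimated correlation), with Arc (-0.74) and Klf10 (-1.04) lower. The postsynaptic list had 7 of 19 higher and 5 lower (8 and 5 adjusted over the list alone, adjusted p = 0.0289, and adjusted p = 0.438 with an estimated correlation), led by Camk2a (0.74) and Dlg4 (0.91). In the interferon list 5 of 8 fell and 1 rose (6 and 1 adjusted over the list alone, adjusted p = 0.0234, and adjusted p = 0.112 with an estimated correlation). Over all comparisons, 35 of 180 list tests passed with the preset correlation and 17 of these with an estimated one; in 25 tests the median, the mean and the test differed in sign, and none of these passed.

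Further rises from P30 to P80 in Soc were in Anp32a (1.82), the platelet chemokine Pf4 (1.67), Zbtb20 (1.42), Fbxw7 (1.35), Brd10 (1.30), Limk1 (1.29), Zdhhc20 (1.26), Thoc2 (1.246), Srek1ip1 (1.23) and Phf14 (1.21). Further falls were in Apc (-1.55), Actr2-ps1 (-1.47), Pank3 (-1.46), the GABA receptor gene Gabbr1 (-1.43), App (-1.40), the water channel Aqp4 (-1.39), Rab6a (-1.29), Ddx3x (-1.27) and Mobp (-1.27). The Gapdh 3' to 5' ratio was 1.52 ± 0.042 in Soc P30 and 1.89 ± 0.091 in Soc P80 (SD, n = 6 each).

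Single age steps in Soc showed the interferon genes as a peak at P40. From P30 to P40 Irf7, Isg15, Lgals3bp, RT1-S3 and Irf9 rose by 2.08, 1.97, 1.54, 1.44 and 1.41, and from P40 to P60 Irf7 and Isg15 each fell by 2.33, Ifitm3 by 1.67 and Lgals3bp by 1.60. Ttr fell by 3.65 in the first step, with RT1-T24-4 (-1.93), App (-1.36), Aqp4 (-1.32) and the kinesin Kif5c (-1.24, with another probe set passing in the opposite direction). In the step to P60 the collagen Col1a1 fell by 1.98, and RT1-T24-4, the proline oxidase Prodh, Lrrc4, Nat8f3 and Arap1 rose by 2.87, 1.13, 0.90, 0.89 and 0.86. For RT1-T24-4 both steps are differences from a level in Soc P40 below the 10th percentile of all signals. From P60 to P80 Anp32a (1.43), R3hdm2 (1.36), Pacsin1 (1.35), Scaf1 (1.32) and Epn1 (1.32) rose, and Slc3a1 (-1.23), Nat8f3 (-1.06), Klf10 (-1.002), Ddx3x (-0.97) and Tiparp (-0.90) fell. In these steps 3265, 6396 and 5412 probe sets passed, with 176, 264 and 367 higher and 193, 578 and 228 lower by over 0.5. In isolated rats 5851 probe sets passed between P30 and P80, 3128 higher and 2723 lower at P80, with 309 higher and 582 lower by over 0.5. Ankrd13d (1.47), Irf7 (1.34), Aff1 (1.17), Fos (1.04) and Brd10 (1.01) rose most, and Kif5c (-1.68), Hbb (-1.61), App (-1.57), Actr2-ps1 (-1.45) and the tight junction protein Cldn11 of myelin (-1.32) fell most.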

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

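The 8 tests of explanations in this part were chosen only after the results had been seen, and the 11 tests of random splits were fixed before.

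Fos, Egr2, Arc and Egr1 were lower in Iso at all 4 ages, and the immediate early list passed at P30, P40 and P60 and not at P80. With RNA integrity as the cause the list would have been higher in Iso at P40, where the Gapdh 3' to 5' ratio was higher, but its median there was -0.271 with 9 members lower. This rests on Gapdh, as the actin and hexokinase ratios did not pass at P40 (adjusted p = 0.538 and 0.565). By that direction at P40, RNA integrity as Gapdh measures it is not a likely cause of the whole. With the Gapdh ratio as a covariate, Fos at P80 stood at -1.325 and Arc at P40 at -1.081, both past the threshold. That fit takes its slope from the samples within groups, so it cannot separate RNA integrity from rearing. A difference in time of day that was the same at every age would have kept the sign of clock genes. Of 12 clock genes, 0 had 1 sign at all 4 ages, but of all probe sets only 7.78% did, so this says little. Time of day at single ages stays open, since clock genes passed in both directions at P60, with Dbp higher and Per2 lower in Iso. Levels that vary between groups at random stay open: on the list means of the 8 groups, with age as a block, the list passed over 30 lists with moderated variances in limma (adjusted p = 0.00505) and not without moderation (unadjusted p = 0.0235, adjusted p = 0.705). Camera on the group means, which sets the list against other genes, passed (adjusted p = 5.37e-61). It takes genes as the unit, so it cannot decide whether levels vary between groups at random. A lower activity of neurons in isolated rats at the time of sampling may be the cause, a hypothesis that recordings or counts of Fos-positive cells in separately measured animals would test.

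Arrays of a group were closely alike. If the arrays of a group were hybridisations of 1 RNA or 1 pool, immediate early genes, which vary between animals, would spread within groups no more than probe sets of like brightness, and the median ratio of their SDs over 17 genes was 1.09. Vgf (3.64), Egr4 (1.93) and Dusp1 (1.57, with 1 low array in Iso P60) spread more, whereas Arc (0.66), Ier5 (0.691), Egr1 (0.699) and Nr4a1 (0.699) spread less, as 1 RNA would give. Arrays 3 and 4 of Iso P30 lay closer (0.116) than all other pairs (0.175 or more). They were also the closest over the spike-ins (0.0613 against 0.0919 or more). The pair may thus share more steps than the RNA, so it cannot decide whether the other arrays share 1 RNA. The question thus stays open. The share of variance between groups was 0.429 for spike-ins, 0.561 for the kept probe sets and 0.156 by chance. The spike-ins, which hold no rat RNA, thus partly followed the groups, so some of the handling of the arrays differed between groups. Whether arrays were run group by group is not given in the labels. How much of the share of the kept probe sets comes from such handling was not tested. The differences between groups may thus hold differences between pools, single animals or runs that the p-values do not count.

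Interferon genes were lower in Iso at P40 and higher at P80. At P40 these genes were raised in Soc (list mean 8.15), whereas Iso (6.89) lay near the groups of P30 and P60. RNA integrity as Gapdh measures it would have raised them most at P60, where that ratio differed most, but the list's median there was 0.0667 against 0.822 at P80. RNA integrity stays open for P80, since the hexokinase ratio, a measure not fixed beforehand, differed at that age alone (permutation test, adjusted p = 0.0173). A change in microglia would have moved the microglia list alike. Its median at P80 was -0.039, which argues against more microglia at that age. At P40 its median was -0.177, and it passed as lower there (camera adjusted p = 0.0327 with an estimated correlation). That is the direction of the interferon list, whose median was -1.373, but a far smaller size. This argues against fewer microglia in Iso as the cause of the whole difference at P40, and a part in it stays open. A single animal among separately measured animals is not a likely cause, as 6 of 6 social arrays at P40 lay above every isolation array of that age. If the arrays of a group share 1 RNA, an infection or immune response in few animals could give such a pattern, a hypothesis that samples taken from each animal would test.

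Random splits gave fewer probe sets than the real groups in every comparison, so that chance can be excluded for the assignment of single arrays to groups, with 1 split of 100, the real one, reaching the real number. The real number and the highest other were 2418 and 1340 at P30, 3443 and 1572 at P40, 6446 and 4245 at P60, 5796 and 3146 at P80, and 3472 and 4 for the mean over ages. For age in Soc they were 3265 and 1284 (P40 against P30), 6396 and 3954 (P60 against P40), 5412 and 2957 (P80 against P60) and 6044 and 3252 (P80 against P30). They were 5851 and 4667 for P80 against P30 in Iso, and 8767 and 92 for the interaction. The splits treat arrays as independent and exclude no chance difference between whole groups: with group means as the unit 0 probe sets passed in limma for the mean over ages (210 at an unadjusted p under 0.05).

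Single samples far from the others of their group, by Dixon's test, were found in 12 of 232 groups of values (5.17%), and chance gives about 1 in 20. The Gapdh 3' to 5' ratio was 1.45 in array 4 of Soc P30 (others 1.52 to 1.57) and 2.33 in array 6 of Soc P60 (others 1.92 to 2.03). Borcs8 was 4.39 in array 2 of Soc P40 (5.94 to 6.69). In Iso P40 Isg15 was 4.89 in array 5 (5.60 to 5.78), Poldip2 2.73 in array 2 (4.84 to 5.58) and Ppm1a 2.87 in array 5 (5.08 to 5.91). In Iso P60 Dusp1 was 7.32 in array 1 (7.86 to 8.12), Id4 7.21 in array 3 (6.51 to 6.67) and Arap1 4.05 in array 5 (5.62 to 5.98). In Iso P80 Mmgt1 was 8.48 in array 4 (8.81 to 8.98), Coa5 10.41 in array 4 (10.16 to 10.25) and Ppp1r26 7.70 in array 5 (7.89 to 7.96).

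The difference by rearing varied between ages, by the interaction test of limma, for 81 of the 83 probe sets named for the 4 rearing comparisons. These were chosen for a large difference at 1 age, which favours an interaction, and of all probe sets 8767 (72.2%) passed. The test cannot tell an interaction apart from other differences between single groups, such as pools or runs. The smallest adjusted p were those of Ifi27 (5.67e-32), Ttr (4.75e-29), Rab3a (5.9e-29), Irf7 (6.59e-29), Vsnl1 (9.91e-27), Syn2 (2.21e-25), Mobp (2.21e-25), Mbp (9.53e-25), Vdac1 (9.8e-25) and Scd2 (1.03e-24).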

How the results depend on the processing

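The size limit, the group means, the close arrays counted apart and the fit without the 3 farthest arrays were chosen only after results had been seen; all other alternatives were fixed before the data were examined. Total counts stayed within 1.5 times under both pseudocounts, no filter, quantile normalization and a prior without trend. The balance of higher and lower calls held less well. With no filter it turned to more lower calls for P60 against P40 (3561 higher, 3894 lower) and P80 against P30 (3739 and 3899) in Soc and P80 against P30 in Iso (3282 and 4116). It turned to more higher calls at P40 and P80 with quantile normalization (1849 and 1804, 2890 and 2797) and the 70th percentile filter (1199 and 1024, 1981 and 1666), and at P40 with the covariate (1861 and 1740). A filter at the 70th percentile, which tests fewer genes, passed 2223 probe sets at P40, 3906 at P60, 3647 at P80, 2245 for the mean over ages, 2055, 3925, 3486 and 3531 for age in Soc (P40 against P30, P60 against P40, P80 against P60, P80 against P30), 3571 for P80 against P30 in Iso and 5154 for the interaction. A log2 difference of at least 0.5 left 136, 360, 1001 and 656 from P30 to P80, 18 for the mean, 369, 842, 595 and 1073 for age in Soc and 891 in Iso. With the Gapdh 3' to 5' ratio as a covariate 1589 passed at P30, 3752 at P60 and 1860 for the mean; the cause was not tested. It reversed Cldn10 (-0.09985) and Gabra5 (0.107) at P60, Htr2c at P80 (-0.06391) and, in the mean, Mlc1 (0.03873), S100b (0.1197), Col1a1 (0.00406), Gabra5 (0.01317), Gabbr2 (0.0289), Cspg5 (-0.01655), Cyc1 (0.02208), Hsp90ab1 (0.04697) and Hspd1 (0.003501). Among the results of named genes and list members, 173 lost their call with this covariate and 566 stayed the same. The cause was not tested. The authors' kind of test passed 2266 at P40 after adjustment and group means as the unit 0 for the mean; the cause was not tested. Quantile normalization reversed the oxidative phosphorylation list at P30 (adjusted p = 0.504) and took the correlation of P30 and P40 past the threshold (0.21); the filter at the 70th percentile took that of P30 and P80 (0.276) below it; the cause was not tested. The replicate block, from numbers that the labels do not tie to litters, batches or days, passed 2391, 3378, 6464 and 5789 from P30 to P80 and 3395 for the mean, and correlations of arrays with the same number lay between -0.0888 and 0.0857. Counted apart, the 2 closely agreeing arrays gave 2772 at P30. Without the 3 farthest arrays 2654, 3013, 6263 and 5963 passed from P30 to P80. With 1 array left out, counts lay between 1881 and 2439 at P30, 2895 and 3329 at P40, 6115 and 6305 at P60, 5482 and 5611 at P80, 3261 and 3537 for the mean, 2852 and 3175, 6050 and 6278, 5089 and 5241, and 5651 and 5940 for age in Soc, 5413 and 5765 in Iso, and 8588 and 8795 for the interaction. Of 35 list calls 17 held with an estimated correlation. The immediate early list at P80 and the astrocyte list for P80 against P30 in Soc passed with the replicate block (adjusted p = 0.0399 and 0.0456), and the GABA receptor list at P30 did not (0.0528). With the mean of all probe sets of a gene 5 list calls were lost, the myelin list at P80 (adjusted p = 0.0643) among them, and 5 gained. Quantile normalization lost 6, the reversed one included, and gained 6, among these the oxidative phosphorylation (0.0028) and ribosomal protein (0.00587) lists at P60 and the immediate early list at P80 (0.0354); the cause was not tested. Genes under the filter, choroid plexus markers among them, are limited by signal over background.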

Other observations

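None of the tests in this part was chosen only after the results had been seen. Haemoglobin Hbb, a marker of blood in the tissue and the only measured gene of the red blood cell list, fell with age in both rearing groups and differed by rearing in both directions. Its signal in Soc was 10.70, 10.47, 9.66 and 9.65 from P30 to P80, and in Iso 10.79, 10.63, 10.11 and 9.18. The serotonin list had only the receptor gene Htr2c, with differences of 0.12, 0.26, -0.40 and 0.20 between Iso and Soc. The choroid plexus list had only Ttr, and the sex-linked list was too small to test; the Y-linked Eif2s3y lay between 8.12 and 8.57 in all 8 groups.

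Several fixed lists passed in none of the 6 comparisons in which lists were tested with camera. Their lowest and highest adjusted p were 0.576 and 0.932 for oligodendrocyte precursors, 0.157 and 0.871 for endothelial cells, 0.357 and 0.864 for pericytes, 0.157 and 0.864 for striatal projection neurons, 0.346 and 0.956 for GABAergic interneurons and 0.0741 and 0.576 for cortical pyramidal neurons. They were 0.458 and 0.864 for glutamate receptors, 0.43 and 0.984 for dopamine and noradrenaline signalling, 0.0728 and 0.903 for the glucocorticoid response and 0.371 and 0.864 for neuronal adhesion. The glucocorticoid response list passed for the mean over ages after quantile normalization (adjusted p = 0.0484). For the cell cycle they were 0.334 and 0.871, for the circadian clock 0.696 and 0.903, and for neurotrophins and neuregulins 0.696 and 0.873. Single members still passed at P80, where 7 of 14 interneuron genes rose and 3 fell (7 and 4 adjusted over the list alone), with Vip at 0.38, Gad1 at 0.28 and Calb2 at 0.48.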
